A study of Drosophila melanogaster with 9 samples.

How the data were processed

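RNA was measured in wing imaginal disc cells of larvae about 8 days old, sorted into anterior, posterior and delaminating populations with 3 biological replicates each, on Affymetrix arrays of the Drosophila genome. Per the labels, cells were dissociated with trypsin, sorted by RFP and GFP fluorescence, and their RNA was amplified as a whole transcriptome and labelled with biotin. The deposited values were log2 signals made by the authors with RMA (background correction, quantile normalization and a summary of the probes of each probe set), as the submitters' processing notes state. The version of RMA was not given in the sources used here. The values were used as deposited, without further scaling, and lay between 2.70 and 14.0 with array medians from 7.48 to 7.57. For arrays the depth of counts does not apply, and their number limited the precision.

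The table held 18952 probe sets, of which 183 control probe sets were left out. Of the 18769 others, 13647 carried 1 gene symbol in the platform's probe table, 402 carried several and 4720 carried none. The table's annotation was updated through gene identifiers to the symbols and chromosome arms of the RefSeq annotation of the Drosophila melanogaster assembly GCF_000001215.4, which matched 11893 of 11982 genes. Where 1094 genes had more than 1 probe set, the set with the highest mean over the 9 arrays was used. Probe sets with several symbols or none were left out of the tests by gene, and entered the alternative in which all probe sets were tested. All 9 arrays entered the fit and 0 were left out.

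Groups were compared with limma 3.58.1 in R 4.3.3 by a linear model with a mean per group and moderated variances, fitted to all 9 arrays. The comparisons were delaminating against posterior, posterior against anterior and delaminating against anterior, each as the difference of group means on the log2 scale. limma's moderated test was two-sided, its p values were adjusted by the Benjamini-Hochberg method over the 11982 genes, and genes with an adjusted p under 0.05 are named as called. A gene was counted as separated where every value of a group lay above every value of the other. Folds are powers of 2 of the log2 differences, and SE is the moderated standard error.

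Gene lists were fixed before the data were examined, 27 of pathways and processes and 6 of cell type markers, and lists with at least 3 measured genes were tested. They were tested against all other genes with camera from limma at a preset correlation of 0.01, adjusted over the 33 lists of a comparison, and again with an estimated correlation. Of the calls with the preset correlation, the posterior identity list in posterior and in delaminating against anterior cells also passed with an estimated correlation. Chromosome arms were tested in the same way. Families of genes that share the start of their symbol were tested only after the data had been seen.

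Genes were named by a rule fixed before the data were examined. It took asp, en, inv, hh, ci, ptc and Mmp1 as checks of the labels, the 8 highest and 8 lowest called and separated genes of each comparison, and up to 4 called genes of each list or up to 2 with the smallest p where a list had no called gene. Where the text names other genes, it says that they were chosen after their values were seen. The overlap of both comparisons with anterior cells was compared with 20 simulations of unchanged groups, drawn with seed 20.

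The procedure was tested on simulated data, with 100 genes planted among 11982 at each size. A planted log2 difference of 1 was recovered for 35% of genes in delaminating against posterior, 51% in posterior against anterior and 46% in delaminating against anterior cells, and a difference of 2 for 97%, 98% and 99%. False calls numbered 5, 10 and 11.

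Alternatives fixed before the data were examined were a replicate block, a filter that left out the dimmest 25% of genes, quantile normalization applied again, centring each array on its median, all probe sets tested, the mean of a gene's probe sets, only the groups compared in the fit, an intensity trend with robust variances, array weights, a log2 difference of at least 1, each of the 9 arrays left out in turn, and the estimated correlation in camera. Leaving out anterior replicate 3 and delaminating replicate 2 together was added after the data had been seen. Figures were drawn with matplotlib 3.10.9.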

Results

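Gene expression was measured on 9 Affymetrix arrays in cells sorted from wing imaginal discs, the larval epithelial sacs from which the adult fly wing forms. The discs came from larvae about 8 days old. In their posterior cells the engrailed-GAL4 driver expressed p35 (a viral protein that blocks caspases), a double-stranded RNA against asp (the gene for the spindle pole protein Abnormal spindle) and the red fluorescent protein RFP. A GFP reporter marked cells with activity of Mmp1, a gene for a secreted matrix metalloproteinase. Flow sorting gave 3 populations with 3 biological replicates each. Anterior cells lacked both fluorescent proteins, posterior cells carried RFP alone, and delaminating cells carried RFP and GFP. As defined, the anterior population could hold any disc cell type without RFP and GFP. The values were log2 signals, with array medians from 7.48 to 7.57, and 11982 genes were tested. The correlation of anterior replicate 3 with the other arrays lay between 0.889 and 0.915, against 0.943 to 0.987 among the other 8. The number of arrays limited the precision of every value. Lower quartiles of the arrays lay between 6.05 and 6.36, and no detection calls were analysed here, so signals below them were not shown to be above background. Where a called gene's mean lay below the lower quartile of every array of its group, its signals are given without a fold.

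The sorting labels were checked first on genes of the compartment boundary. en, which specifies posterior identity and whose driver was used for the sort, lay at 7.16 ± 0.31 in anterior, 10.54 ± 0.09 in posterior and 10.43 ± 0.53 in delaminating cells (mean log2 signal ± SD, n = 3 arrays per group). Its paralog inv, at 7.63 ± 0.32, 9.65 ± 0.10 and 9.26 ± 0.29 in the same order, and the posterior ligand gene hh, at 7.01 ± 0.29, 9.11 ± 0.10 and 9.64 ± 0.33, followed the same order of anterior below both others. ci, the anterior transcription factor of Hedgehog signalling, ran the other way, at 9.97 ± 0.31, 8.33 ± 0.02 and 7.90 ± 0.13. The Hedgehog receptor gene ptc differed less, with 11.99 ± 0.06, 11.59 ± 0.14 and 11.22 ± 0.30. It was called in neither comparison with anterior cells, so it lends the labels no support. The targeted gene asp and the reporter gene Mmp1 were not analysed here, because no probe set was assigned to either name in the probe table used. The probe set of en is of a type that can match several transcripts.

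**Figure D1:**
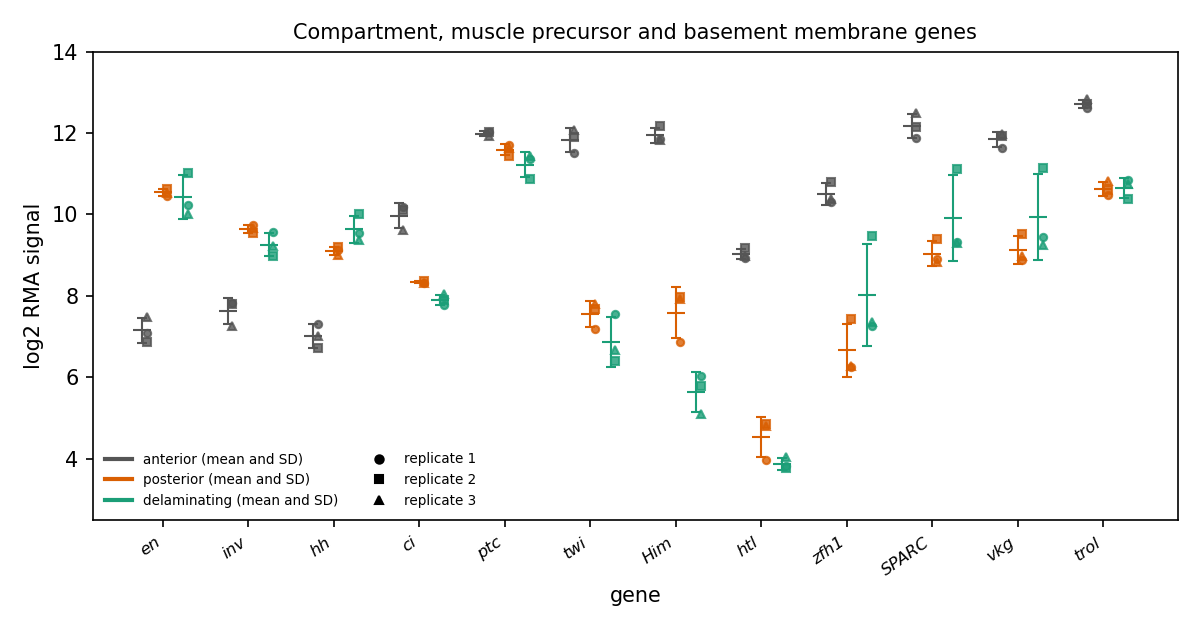
Log2 signal (vertical axis) of compartment, muscle precursor and basement membrane genes (horizontal axis) in anterior, posterior and delaminating cells. Points are single arrays, with a shape for each replicate number, and bars give the mean and SD of 3 arrays. en has means of 7.16 in anterior and 10.54 in posterior cells, and htl has means of 9.04 and 4.54.

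Delaminating cells were compared with posterior cells, which carried the same transgenes but no reporter signal, to find transcripts that mark the cells leaving the epithelium. Of 24 measured secreted signal genes, 4 were called higher in delaminating cells, and the list passed (camera adjusted p = 7.79e-10, adjusted p = 0.0852 with an estimated correlation). upd1, a gene on the X chromosome for a ligand of the JAK/STAT pathway, was 6.83-fold higher, at 11.12 ± 0.29 against 8.35 ± 0.75 (mean log2 signal ± SD, n = 3 arrays per group, limma adjusted p = 0.0107). Pvf1, a ligand related to PDGF and VEGF, was 4.01-fold higher (8.31 ± 0.18 against 6.31 ± 0.11, adjusted p = 0.00446). scaf, a serine protease homolog induced by JNK signalling, was 8.23-fold higher (3.04 ± 0.34 SE, adjusted p = 0.00519). In the opposite direction, the Iroquois homeobox gene mirr was 3.54-fold lower (adjusted p = 0.0381) and the zinc finger gene tsh, which acts in the proximal wing and body wall, was 2.16-fold lower (adjusted p = 0.0283).

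Of 11982 genes, 77 were called higher and 19 lower in delaminating than in posterior cells at a Benjamini-Hochberg adjusted p under 0.05, and all 96 had their 3 values in each group entirely apart. The balance of directions varied over the alternatives, from 431 higher and 318 lower with array weights to 20 and 0 without posterior replicate 2. At an unadjusted p under 0.05 there were 1196 genes, and separation held for 22.3% of all genes, against 10% by chance for 3 arrays against 3. CG10126, a gene known here only by its number, rose to 10.83 ± 0.70 from 5.61 ± 0.56, a posterior signal below the lower quartile (adjusted p = 0.00519). CG15279 rose 15.2-fold, CG15021 rose 7.31-fold, and vir-1, which is induced in flies by viral infection, rose 7.78-fold, with adjusted p between 0.00142 and 0.00282 for the 3 genes. flap rose 6.46-fold and Idgf3, an imaginal disc growth factor of the chitinase-like family, rose 5.63-fold (adjusted p = 0.0469). Another probe set of Idgf3 differed by 0.44, its call was lost in 12 of 19 alternative settings, the mean of its probe sets among them, and its highest value was that of delaminating replicate 2 (9.96 against 8.35 and 8.48). Falls among called genes included those of CG15212 at 5.07-fold and of the serpin gene Spn43Aa at 4.10-fold. Him, a gene that holds muscle precursors undifferentiated, fell to 5.64 ± 0.49, below the lower quartile, from 7.59 ± 0.63. CG43980 fell by 2.78-fold, the sulfotransferase gene pip by 2.67-fold, the T-box gene Doc2 by 2.52-fold and the protease gene Np by 2.48-fold, with adjusted p between 0.0313 and 0.0465. The 10 probe sets of pip ranged from -1.42 to -0.14, and pip, mirr and Np lost their calls with the mean of a gene's probe sets.

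Among fixed gene lists, the secreted signal list had 8 of 24 genes higher when adjusted over the list alone. Those called over all genes were upd1, Idgf3, Pvf1 and upd2, the last 3.88-fold higher at adjusted p = 0.0479, and the list had a median log2 difference of 0.73. Of 9 JNK target genes, scaf and Jra, which encodes the fly Jun, were called higher, Jra by 2.14-fold at adjusted p = 0.0353. In that list 7 genes were higher when adjusted over the list alone, and its camera adjusted p was 2.9e-09 (adjusted p = 0.0852 with an estimated correlation). Mmp1, whose reporter set the sort, was itself named in this list, though no probe set measured it. The sort thus selected cells on a listed JNK target, and the rise of the list is not independent of the sort. In the apoptosis list 1 of 13 genes passed, the cell death gene skl, at 5.66 ± 0.16 against 4.70 ± 0.10, both below the lower quartile (adjusted p = 0.0381), with 5 higher when adjusted over the list alone (list camera adjusted p = 3.96e-05, adjusted p = 0.0852 with an estimated correlation). The actomyosin list had 1 gene of 18 called, Arpc1 of the actin-nucleating Arp2/3 complex, at 2.06-fold higher, and 9 when adjusted over the list alone (camera adjusted p = 1.41e-08, adjusted p = 0.402 with an estimated correlation). Among 35 genes of oxidative stress defence, the glutathione transferase gene GstD6 rose 2.51-fold and Men, the malic enzyme that makes NADPH, rose 2.43-fold (list camera adjusted p = 0.000191, adjusted p = 0.5 with an estimated correlation). Adjusted over the list alone, 6 of the 35 were higher and 1 lower.

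Wing patterning genes moved down as a list, with mirr and tsh called of 22 and 7 lower when adjusted over the list alone (camera adjusted p = 0.000126, adjusted p = 0.418 with an estimated correlation). Of 30 DNA replication genes limma called 0 over all genes and 0 when adjusted over the list alone, with 3 lower at an unadjusted p under 0.05, and the list's median was -0.29 (camera adjusted p = 0.000168, adjusted p = 0.418 with an estimated correlation). Mcm2, a subunit of the replicative helicase, had a difference of -0.59 at adjusted p = 0.29. The proteasome list, with 22 of 26 genes above 0, had a median of 0.23, with 0 genes called by limma either way and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.00177, adjusted p = 0.673 with an estimated correlation). The immune list of 18 genes (camera adjusted p = 0.00911) and the anterior identity list of 4 (camera adjusted p = 0.0307) also passed, at medians of 0.25 and -0.40, and both had an adjusted p = 0.418 with an estimated correlation. Over all genes limma called 0 in either list, against 3 immune genes higher and 2 anterior genes lower at an unadjusted p under 0.05. kn, a transcription factor gene of the central wing, was called lower when adjusted over the anterior list alone (difference -1.39, adjusted p over all genes = 0.0791), and 0 immune genes were. Another probe set of kn differed by -0.01 in this comparison. The anterior list lost its call without anterior replicate 3 (adjusted p = 0.099), delaminating 1 (0.0548), delaminating 2 (0.0554) or posterior 1 (0.0525), within a range of 0.0165 to 0.418 over all its alternatives.

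Among cell type markers, Him and the cell adhesion gene hbs were called lower of 8 muscle precursor markers, hbs by 2.41-fold at adjusted p = 0.0465, with 4 lower when adjusted over the list alone (camera adjusted p = 0.000234, adjusted p = 0.402 with an estimated correlation). The 12 hemocyte markers, genes of larval blood cells, had a median log2 difference of 1.43 with 11 of 12 above 0, 0 called by limma over all genes or when adjusted over the list alone, and 4 higher at an unadjusted p under 0.05 (camera adjusted p = 0.000577, adjusted p = 0.666 with an estimated correlation). Delaminating replicate 2 had the highest value of its group for all 12. Without that array the hemocyte list had a camera adjusted p of 0.406, in a range of 9.13e-08 to 0.666 over its alternatives, and the immune list 0.148, in a range of 0.00138 to 0.418. The glia list passed at a camera adjusted p of 0.0455 with a median of 0.32 over 4 genes (adjusted p = 0.418 with an estimated correlation), and its gene moody, a receptor of the blood-brain barrier, had a difference of 2.13 at adjusted p = 0.0576. That gene was called when adjusted over the list alone, the 1 of 4 also past an unadjusted p under 0.05. All 4 genes lay above 0, but repo of that list had signals from 4.98 to 5.75 over the 9 arrays, below the lower quartiles. The shift of the list thus does not show glial RNA. The glia list lost its call without delaminating replicate 1 (0.0935), delaminating 3 (0.087), posterior 2 (0.0599) or posterior 3 (0.0734), in a range of 0.00537 to 0.418.

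The remaining lists did not pass in delaminating against posterior cells. Camera adjusted p was 0.0528 for 22 extracellular matrix and integrin genes and for 18 genes of the nucleolus and ribosome biogenesis. It was 0.0953 for the JNK and p38 pathway, JAK/STAT and Notch target lists, and 0.103 for mitosis and for oxidative phosphorylation. The DNA damage and autophagy lists had 0.291, ecdysone genes 0.28, ER stress 0.418, Hippo targets 0.438, glycolysis 0.731, heat shock 0.778, junctions and polarity 0.818, ribosomal proteins 0.905 and posterior identity 0.971. Trachea markers had 0.778, fat body markers 0.816 and neuron markers 0.905. Adjusted over the list alone, 3 JAK/STAT genes and 3 matrix and integrin genes were higher, 2 ecdysone genes were higher and 3 lower, and 1 gene was higher in each of the JNK and p38, DNA damage and glycolysis lists. Of the JAK/STAT list, upd1 and upd2 were called over all genes, while its median of -0.01 and its mean of 0.48 differed in sign. Median and test direction also differed for posterior identity (median -0.11, direction up), for trachea (0.05, down), for fat body markers (0.08, down) and for junctions and polarity (-0.0019, up).

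**Figure D2:**
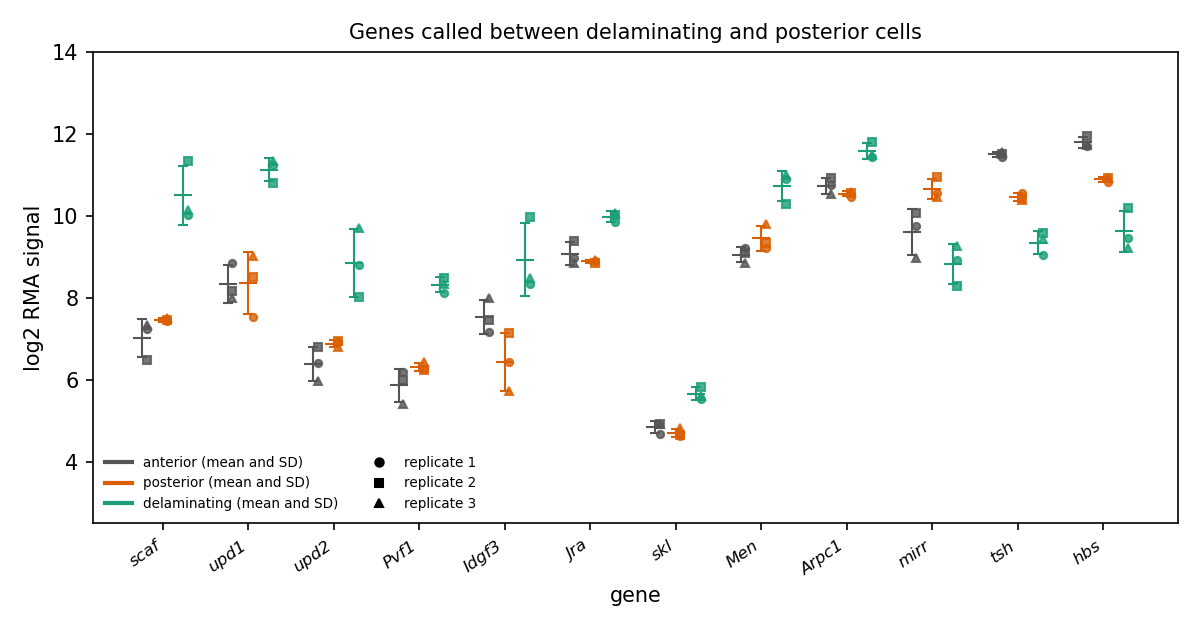
Log2 signal (vertical axis) of 12 genes called in delaminating against posterior cells (horizontal axis), in the 3 sorted populations. Points are single arrays and bars give the mean and SD of 3 arrays. scaf has means of 10.50 in delaminating and 7.46 in posterior cells, and tsh has means of 9.34 and 10.45.

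The number of genes called in this comparison depended on each array. It fell from 96 to 51 without anterior replicate 1, 47 without anterior 2, 26 without delaminating 1 and 47 without delaminating 2. It was 17 without delaminating 3, 18 without posterior 1, 20 without posterior 2 and 32 without posterior 3, and rose to 281 without anterior 3. Anterior arrays enter this comparison only through the shared spread, so leaving one out left the log2 differences unchanged. Anterior 3 had the largest root mean square deviation from its group mean, at 0.53, so the rise to 281 reflects a smaller estimate of the spread. With a replicate block 66 genes were called, 47 of the 96 among them. upd1 lost its call without delaminating 1, delaminating 3 or posterior 2, with an adjusted p of up to 0.0807, and of the 25 named genes called, 7 kept their call in all 19 alternative settings (CG10126, CG15279, scaf, vir-1, CG15021, flap and Pvf1).

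Posterior cells were then compared with anterior cells of discs with the same transgenes. This asks what distinguishes cells with asp double-stranded RNA and p35 from cells without them. Compartment identity and the cell types in each sorted population are parts of the same contrast. Markers of muscle precursors, the mesodermal cells that lie under the notum part of the disc epithelium, were called lower in posterior cells for 4 of 8 genes, with 2 of 8 above 0 (list camera adjusted p = 1.85e-10, adjusted p = 0.113 with an estimated correlation). htl, an FGF receptor gene, lay at 4.54 ± 0.50, below the arrays' lower quartile, against 9.04 ± 0.12 in anterior cells (mean log2 signal ± SD, n = 3 arrays per group, limma adjusted p = 5.27e-05). Him was 20.5-fold lower (log2 difference -4.36 ± 0.33 SE, adjusted p = 0.000221), and the mesodermal transcription factor gene twi was 19.4-fold lower (-4.27 ± 0.31 SE, adjusted p = 0.000185). Genes of posterior identity were higher, with en at 10.4-fold (adjusted p = 0.000288), hh at 4.27-fold (adjusted p = 0.00152) and inv at 4.05-fold (adjusted p = 0.00165). ci was 3.12-fold lower (adjusted p = 0.00239), and ptc had a difference of -0.40 at adjusted p = 0.531.

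In posterior against anterior cells 11 genes were called higher and 58 lower of 11982. That balance varied over the alternatives, from 5 higher and 46 lower without posterior replicate 3 to 195 and 232 with array weights. All 69 had fully separate groups, which held for 18.4% of all genes against 10% by chance. Besides en, hh and inv, called higher were the transcription factor genes kn, at 8.63 ± 0.51 against 6.10 ± 0.48 (adjusted p = 0.00337), the anterior signal below the lower quartile, and Poxn, of the Pax family, at 4.21-fold (adjusted p = 0.0168), and Sara, which encodes an adaptor of TGF-beta signalling, at 2.95-fold (adjusted p = 0.00629). CG43394 was 2.58-fold higher, and dsx-c73A lay at 6.62 ± 0.37 against an anterior signal of 5.36 ± 0.25 below the lower quartile. Another probe set of CG43394 differed by 0.03, and its call was lost with the mean of its probe sets. Another probe set of kn differed by -0.09, so the rise of kn rested on the brighter of its probe sets. Among called genes the lowest after htl, Him and twi were the zinc finger gene zfh1 (log2 difference -3.83), the Enhancer of split gene E(spl)m6-BFM at 12.8-fold, Sox100B, with a posterior signal of 3.81 ± 0.03 that lay below the arrays' lower quartile against 7.24 ± 0.36, the translation elongation factor gene eEF1alpha2 at 9.45-fold and SPARC, a basement membrane glycoprotein, at 8.75-fold. Their adjusted p lay between 5.27e-05 and 0.0124.

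By list, 6 of 8 muscle precursor markers were lower when adjusted over the list alone, at a median log2 difference of -2.36. All 3 posterior identity genes were called higher, also when adjusted over the list alone (camera adjusted p = 2.89e-09, adjusted p = 0.0217 with an estimated correlation). The 13 Notch target genes had 3 called lower and 1 higher, and 5 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.61e-05, adjusted p = 0.362 with an estimated correlation). Beside E(spl)m6-BFM the lower genes were the homeobox gene ct at 3.61-fold (adjusted p = 0.0365) and E(spl)m5-HLH at 3.43-fold (adjusted p = 0.0327). Tom, a Bearded family gene, was 2.05-fold higher (adjusted p = 0.0345). A difference in cell types between the sorted populations was not separated from the shift of the Notch target list. Of 22 extracellular matrix and integrin genes, SPARC, vkg and trol were called lower and none higher (camera adjusted p = 0.00175, adjusted p = 0.786 with an estimated correlation). Adjusted over the list alone, 4 were lower and 1 higher. vkg, a type IV collagen chain, was 6.58-fold lower (adjusted p = 0.0243) and trol, the fly perlecan, 4.23-fold lower (adjusted p = 0.000561). The 8 probe sets of trol ranged from -3.10 to 0.26.

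Single genes of other lists also passed in posterior against anterior cells. egr, the fly TNF ligand, was 2.53-fold lower (adjusted p = 0.0345) but lost its call with the mean of its probe sets, the FGF ligand gene ths 2.83-fold lower (adjusted p = 0.0353) and tsh 2.06-fold lower (adjusted p = 0.0319). Of 24 secreted signal genes, hh was called higher and egr and ths lower, with 3 higher and 2 lower when adjusted over the list alone. egr was the gene called of 19 in the JNK and p38 pathway, with 3 higher and 2 lower when adjusted over the list alone. ct and tsh were called of 22 wing patterning genes, with 3 higher and 3 lower when adjusted over the list alone, and 1 of 9 JNK targets was lower when adjusted over the list alone. The anterior identity list held kn as higher and ci as lower, also when adjusted over the list alone (camera adjusted p = 0.424).

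Further lists shifted up in posterior cells, while limma called 0 of their genes over all genes. Oxidative stress defence had 31 of 35 genes above 0, 5 higher at an unadjusted p under 0.05 and 3 when adjusted over the list alone (camera adjusted p = 0.00175, adjusted p = 0.786 with an estimated correlation). GstE7 and GstE6, which encode glutathione transferases, had differences of 1.02 and 1.56 there. Trachea markers had 4 of 6 higher when adjusted over the list alone and at an unadjusted p under 0.05 (camera adjusted p = 0.00166, adjusted p = 0.501 with an estimated correlation). Gasp, a chitin-binding protein gene of that list, had a difference of 1.72. Of the 6 markers 5 lay above 0, and btl lay between 8.59 and 9.06 in the anterior and posterior arrays. All 6 were brighter than the median gene in posterior cells, so a shift of the list does not by itself show tracheal RNA. Glia markers had 2 of 4 higher by both measures (camera adjusted p = 0.04, adjusted p = 0.592 with an estimated correlation). Of that list, repo lay below the lower quartiles in every array.

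Of 19 junction and polarity genes 6 were higher at an unadjusted p under 0.05 (camera adjusted p = 0.0189, adjusted p = 0.786 with an estimated correlation). The proteasome had 25 of 26 genes above 0 and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0203, adjusted p = 0.786 with an estimated correlation). Of 22 DNA damage repair and 33 mitosis genes, 2 and 1 were higher at an unadjusted p under 0.05 (both camera adjusted p = 0.0266, adjusted p = 0.786 with an estimated correlation). DNA replication had 2 of 30 (camera adjusted p = 0.0491, adjusted p = 0.786 with an estimated correlation). Adjusted over the list alone, 0 genes of these 5 lists passed. Without anterior replicate 3, 6 lists passed in place of 12, and the 6 lost were these 5 and the glia markers, with a camera adjusted p between 0.0708 for glia and 0.501 for mitosis. Without posterior replicate 1 the DNA damage, mitosis and DNA replication lists had 0.0583 and glia 0.0737, without posterior 2 junctions had 0.056 and DNA replication 0.0704, and DNA replication also lost its call without anterior 2 (0.094), delaminating 3 (0.0535) or posterior 3 (0.086). The median difference of all genes was 0.09, and 0.01 without anterior replicate 3.

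Lists that did not pass in posterior against anterior cells had a camera adjusted p of 0.0755 for fat body markers, 0.131 for autophagy, 0.139 for ER stress, and 0.148 for JAK/STAT and for nucleolar genes. Hippo targets had 0.267, glycolysis and ribosomal proteins 0.383, the JNK and p38 pathway and hemocyte markers 0.424, neuron markers 0.479 and heat shock 0.538. Ecdysone genes had 0.663, and secreted signals, apoptosis, oxidative phosphorylation and wing patterning genes 0.711. The immune list had 0.793, actomyosin 0.882 and JNK targets 0.996. Median and direction differed in sign for JNK targets (median 0.20, direction down), wing patterning (0.05, down) and immune genes (0.03, down), and anterior identity had a median of -0.15 and a mean of 0.15.

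The count of 69 fell to 38 without anterior replicate 2, 35 without posterior 1 and 37 without posterior 2, and compartment, transgenes and the cell types in each sorted population could not be separated in this contrast. Muscle precursor markers had a median log2 difference of -2.36, and 4 of them, zfh1 included, were among the 58 lower genes, as were SPARC, vkg, trol and E(spl)m6-BFM. The 58 were selected for being lower, so a common direction with that list was fixed in advance and shows no source for them. Of 25 named genes called, 13 kept their call in each alternative setting that tested them, namely en, inv, hh, ci, kn, Sara, htl, Him, twi, E(spl)m6-BFM, Sox100B, eEF1alpha2 and trol. The filter of the dimmest 25% of genes left 22 of the 25 to test.

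Delaminating cells were last compared with anterior cells, a difference that is the sum of the 2 contrasts above. The secreted insulin-like gene Ilp8, which delays metamorphosis when discs are damaged, was 9.13-fold higher, at 12.29 ± 0.08 in delaminating against 9.10 ± 1.58 in anterior cells (mean log2 signal ± SD, n = 3 arrays per group, limma adjusted p = 0.0211). Its fold was 16.3 without anterior replicate 1 and 5.51 without anterior 3. scaf was 11.1-fold higher (log2 difference 3.47 ± 0.34 SE, adjusted p = 0.000602), and the JNK pathway genes Ets21C, an ETS transcription factor, and puc, the JNK phosphatase, were 3.46-fold and 2.04-fold higher (adjusted p = 0.00691 and 0.0176). upd1 was 6.88-fold and upd2 5.45-fold higher (adjusted p = 0.00316 and 0.006), and Pvf1 lay at 8.31 ± 0.18 against an anterior signal of 5.86 ± 0.40 below the lower quartile (adjusted p = 0.000302). twi was 31.0-fold lower (adjusted p = 4.59e-05). Him, at 5.64 ± 0.49 against 11.95 ± 0.19, and htl, at 3.88 ± 0.14 against 9.04 ± 0.12, were lower with delaminating signals below the arrays' lower quartile (adjusted p = 2.49e-05 and 1.63e-05).

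In all, 287 genes were called higher and 171 lower in delaminating than in anterior cells. The 458 all had separate groups, which held for 21.2% of all genes against 10% by chance. Among the highest were CG10126 at 20.5-fold (12.4-fold without anterior replicate 2), CG15279 at 13.3-fold, moody at 10.8-fold, en at 9.65-fold, CG17124 at 9.27-fold and CG10527 at 8.81-fold, with adjusted p between 0.000221 and 0.00336. Called lower beside the muscle precursor genes were CG34247 at 14.8-fold, the cell surface gene beat-IIIc at 14.5-fold, eEF1alpha2 at 13.7-fold, E(spl)m6-BFM (log2 difference -3.70) and Hesr, a gene related to Hairy and Enhancer of split, whose delaminating signal of 5.39 ± 0.62 lay below the lower quartile against 8.80 ± 0.65. hh was 6.17-fold and inv 3.10-fold higher, ci was lower (log2 difference -2.07, adjusted p = 0.000316), and ptc had a difference of -0.76 at adjusted p = 0.0532.

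Secreted signals had 10 of 24 genes called higher and 1 lower, with 12 and 2 when adjusted over the list alone (camera adjusted p = 1.32e-05, adjusted p = 0.178 with an estimated correlation). JNK targets had 5 of 9 called higher, and 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.6e-05, adjusted p = 0.16 with an estimated correlation). Here too the sort had selected on the reporter of Mmp1, a gene named in that list. Oxidative stress defence had 7 of 35 called higher, and 13 higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.08e-07, adjusted p = 0.338 with an estimated correlation). The glutathione transferase genes GstE6, GstE1 and GstE7 were 7.07-fold, 3.66-fold and 2.85-fold higher, and Men 3.19-fold. Of 18 actomyosin genes 5 were called higher, 11 when adjusted over the list alone (camera adjusted p = 1.03e-05, adjusted p = 0.407 with an estimated correlation). dia, a formin, was 3.17-fold higher, ena, which binds growing actin ends, 2.58-fold, the capping protein gene cpa 2.37-fold and the myosin light chain gene Mlc-c 2.18-fold.

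Cell death and DNA damage genes were also called in delaminating against anterior cells. Corp, a gene of the p53 pathway, was 3.11-fold higher (adjusted p = 0.00375), and the initiator caspase gene Dronc 2.17-fold (adjusted p = 0.0263), while skl rose to 5.66 ± 0.16 from 4.84 ± 0.15, both below the lower quartile (adjusted p = 0.0234). These were 3 of 13 apoptosis genes, 5 when adjusted over the list alone (camera adjusted p = 0.00034, adjusted p = 0.16 with an estimated correlation). Of 22 DNA damage repair genes 3 were called, 5 when adjusted over the list alone (camera adjusted p = 0.00895, adjusted p = 0.407 with an estimated correlation). They were Corp, the double-strand break gene nbs at 2.18-fold and the end-joining gene Ku80 at 2.28-fold (adjusted p = 0.0482). The proteasome list rose with 25 of 26 genes above 0, with 0 called by limma over all genes or when adjusted over the list alone and 13 at an unadjusted p under 0.05 (camera adjusted p = 9.74e-06, adjusted p = 0.407 with an estimated correlation).

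Muscle precursor markers had 6 of 8 genes called lower, 7 when adjusted over the list alone (camera adjusted p = 6.46e-12, adjusted p = 0.0839 with an estimated correlation), and zfh1 was 5.50-fold lower (9.07-fold without delaminating replicate 2). The 3 posterior identity genes were all called higher, also when adjusted over the list alone (camera adjusted p = 5.31e-07, adjusted p = 0.0493 with an estimated correlation). Wing patterning had 2 of 22 called lower, tsh by 4.45-fold and ct by 3.63-fold, and 7 when adjusted over the list alone (camera adjusted p = 0.00161, adjusted p = 0.407 with an estimated correlation). Notch targets had E(spl)m6-BFM and ct lower and Tom 2.32-fold higher, with 4 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00895, adjusted p = 0.407 with an estimated correlation). Of extracellular matrix genes SPARC was 4.77-fold, trol 4.17-fold and vkg 3.74-fold lower, while the metalloproteinase gene Mmp2 was 2.16-fold higher, with 4 higher and 6 lower when adjusted over the list alone (list camera adjusted p = 0.127). Another probe set of Mmp2 had a difference of -0.03, and with the mean of its probe sets its adjusted p was 0.106. Within delaminating cells, replicate 2 had the highest zfh1, SPARC and vkg, as it had for the hemocyte markers, and without it SPARC was 7.26-fold and vkg 5.67-fold lower.

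Further lists passed in this comparison. Trachea markers had Gasp at 4.27-fold and serp at 1.85-fold higher, both genes of the chitin matrix, and 3 of 6 higher when adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.407 with an estimated correlation). Glia markers had moody called and 2 of 4 higher when adjusted over the list alone (camera adjusted p = 0.00222, adjusted p = 0.178 with an estimated correlation). With repo below the lower quartiles in every array, the glia list does not show glial RNA. The trachea list does not by itself show tracheal RNA. JAK/STAT had upd1 and upd2 called of 9 and 3 when adjusted over the list alone (camera adjusted p = 0.00599, adjusted p = 0.407 with an estimated correlation). The JNK and p38 pathway had the TNF receptor gene grnd at 2.59-fold and the stress response gene Gadd45 at 1.91-fold higher, with 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0346, adjusted p = 0.486 with an estimated correlation). Autophagy had Atg16 at 1.98-fold higher, and 1 gene when adjusted over the list alone (camera adjusted p = 0.0182, adjusted p = 0.486 with an estimated correlation).

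Another 4 lists passed with 0 genes called by limma over all genes or when adjusted over the list alone. At an unadjusted p under 0.05, 5 of 18 nucleolar genes were higher (camera adjusted p = 0.00391, adjusted p = 0.407 with an estimated correlation). Of junction and polarity genes 6 were higher and 1 lower (camera adjusted p = 0.0131, adjusted p = 0.598 with an estimated correlation). Of ER stress genes 3 were higher (camera adjusted p = 0.0346, adjusted p = 0.611 with an estimated correlation), and of hemocyte markers 2 (camera adjusted p = 0.0342, adjusted p = 0.646 with an estimated correlation). Without anterior replicate 3, 13 lists passed in place of 20. Lists that lost their call without that array were JAK/STAT, trachea and DNA damage (each 0.0519), the JNK and p38 pathway (0.11), autophagy, junctions and hemocyte markers (each 0.118) and ER stress (0.248). Without delaminating replicate 2 the camera adjusted p was 0.228 for the JNK and p38 pathway, 0.18 for ER stress, 0.0716 for autophagy and 0.0618 for junctions. The hemocyte list then turned downward at 0.988 and reached 0.122 without anterior 1, in a range of 0.00082 to 0.988.

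The ecdysone list did not shift (camera adjusted p = 0.538) but held genes called in both directions, 2 higher and 2 lower, with 2 and 5 when adjusted over the list alone. Cyp18a1, which inactivates ecdysone, was higher at 8.10 ± 0.50 against an anterior signal of 5.38 ± 0.37 below the lower quartile, and ImpL2, a secreted antagonist of insulin signalling, was higher by a log2 difference of 1.43. ImpL1, an ecdysone-inducible gene, was 2.20-fold and the nuclear receptor gene Eip78C 1.98-fold lower. In the immune list pirk, a brake on the Imd pathway, was 2.23-fold higher and 2 genes were higher when adjusted over the list alone (camera adjusted p = 0.0577). Of the other lists, fat body markers had a camera adjusted p of 0.0686, oxidative phosphorylation 0.0954, anterior identity 0.133, DNA replication 0.208 and ribosomal proteins 0.335. Glycolysis, mitosis and neuron markers had 0.538, heat shock 0.711 and Hippo targets 0.78. Adjusted over the list alone, 1 anterior identity gene was higher and 2 lower, 1 Hippo target was higher and 1 fat body marker lower. Median and direction or mean differed in sign for Hippo targets (median -0.02, direction up), neuron markers (0.09, down) and ecdysone genes (median -0.06, mean 0.05).

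The count of 458 fell to 286 without anterior replicate 2, 244 without delaminating 1 and 212 without delaminating 3, and to 180 when the fit used only the 6 arrays compared. Of 55 named genes called, 33 kept their call in all 19 alternative settings, while Ilp8 and puc lost it with those 6 arrays and without anterior 2, delaminating 1 or delaminating 3, and Ilp8 without delaminating 2, with an adjusted p of up to 0.0797 and 0.0803.

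The hemocyte markers varied more between arrays than between populations. In delaminating cells PPO2, the prophenoloxidase of crystal cells, lay at 11.8 in replicate 2 against 7.25 and 7.65 in replicates 1 and 3, and Hml, a hemocyte adhesion protein, at 10.4 against 8.44 and 7.52. Replicate 2 also held the highest value of its group for 7 of 12 markers in anterior and 9 of 12 in posterior cells.

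**Figure D3:**
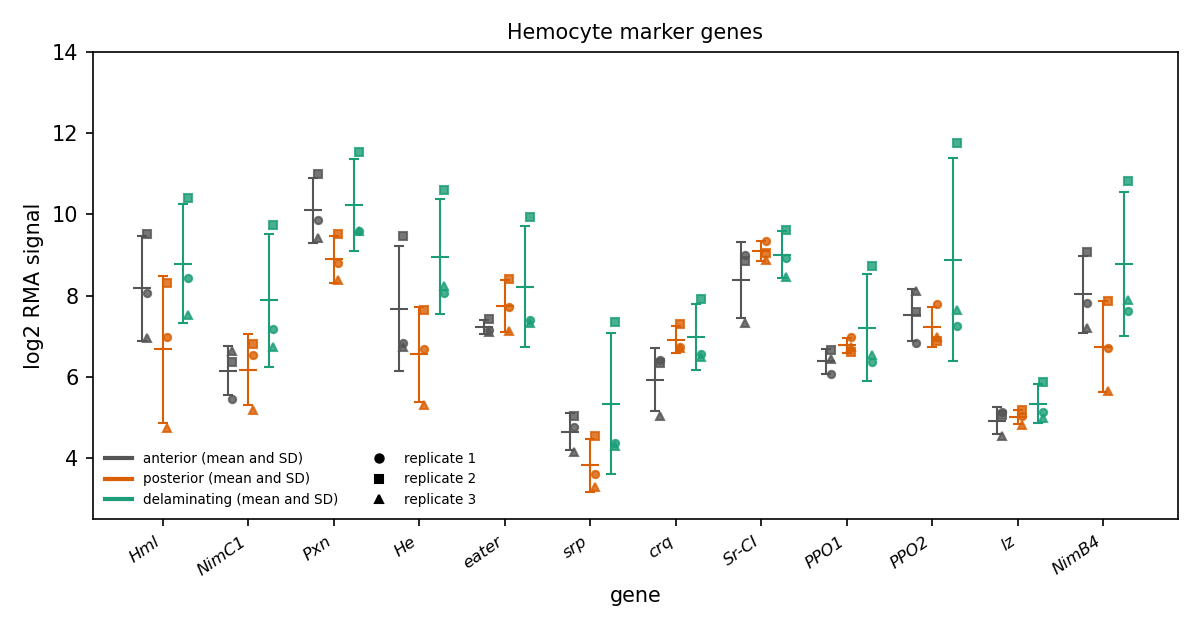
Log2 signal (vertical axis) of 12 hemocyte marker genes (horizontal axis) in the 3 sorted populations. Points are single arrays, with a shape for each replicate number, and bars give the mean and SD of 3 arrays. Delaminating replicate 2 is highest of its group for all 12 genes, with PPO2 at 11.8 and Hml at 10.4.

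Both populations that carried RFP shared many differences from anterior cells. In both comparisons 53 genes were called lower and 9 higher, and 0 in opposite directions. Independent lists of the same lengths would share 0.828 lower and 0.263 higher. In 20 simulations all 9 arrays were drawn without group differences, with the simulated anterior arrays shared by both comparisons. They gave means of 0 and 0.05. With no differences few genes are called in either comparison, so means near 0 were fixed in advance. They do not show what shared anterior arrays add to the counts. Among the shared lower genes were Him, htl, twi, zfh1, SPARC, vkg, trol, ct and tsh, and the shared higher genes included en, hh, inv, Poxn, Sara and Tom. Of these, Him, htl, twi and zfh1 are themselves muscle precursor markers, a list with medians of -2.36 in posterior and -2.31 in delaminating against anterior cells. The shared lower genes were selected for being lower, so a common direction with that list says nothing about the source of the others. Across genes, which are not independent replicates, the 2 sets of log2 differences had a correlation of 0.682 against 0.499 in the simulations, and a covariance of 0.148 against 0.0376. The simulations gave every array the same spread for a gene. Root mean square deviations from the group mean were 0.32, 0.32 and 0.53 in anterior arrays, against 0.19 to 0.33 in the others. Extra noise in the shared anterior arrays was thus left out, and the excess over the simulations cannot be read as shared differences. The 3 anterior arrays could not be split into parts of at least 2, so part or all of the excess may come from the shared controls. The 62 shared genes became 33 without anterior replicate 2, 32 without posterior 1, 35 without posterior 2 and 40 without posterior 3.

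The title of the series concerns gene dosage, so the genes of each chromosome arm were tested together. Of 6 arms in 3 comparisons, only the 65 genes of chromosome 4 passed, in delaminating against posterior cells, with a median log2 difference of -0.10 (camera adjusted p = 0.048, adjusted p = 0.949 with an estimated correlation). That call was lost without the dimmest 25% of genes (0.116), with quantile normalization applied again (0.0506) and without delaminating replicate 1, delaminating 3 or posterior 2, in a range of 0.000228 to 0.949. The medians of the other 5 arms in that comparison lay between -0.04 and 0.02. Each array averages many sorted cells, so changes of an arm that differ from cell to cell could cancel and were not addressed.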

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

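The tests of anterior replicate 3 and of the hemocyte genes were chosen after their results had been seen, while the other splits of the samples were planned. Probe sets without a gene name were outside the comparisons by gene. When all probe sets were tested, 10 of these 4720 were called in delaminating against posterior cells (7 higher, 3 lower) of 71 in all, 29 in posterior against anterior cells (5 higher, 24 lower) of 129, and 152 in delaminating against anterior cells (48 higher, 104 lower) of 709.

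For each comparison the 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. A mixed split also places any real difference between the groups in the spread, which lowers its count. Where the groups differ, a low count in mixed splits is thus fixed in advance, and these counts lend no support. In delaminating against posterior cells 1 split of 10, the real one with 96 genes, gave as many genes, and the highest of the others gave 0. In posterior against anterior cells it was also 1 split, the real one with 69 genes, with 0 as the highest other. In delaminating against anterior cells it was again 1 split, the real one with 458 genes, with 0 as the highest other.

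Anterior replicate 3 had correlations of 0.889 to 0.915 with the other arrays and an SD of 1.83 over its probe sets, against 2.01 to 2.08 elsewhere. A narrower range of signal in that array is a candidate explanation. The slope of its difference from the posterior mean on that mean was -0.197, against -0.04 and -0.01 in the other anterior arrays. This slope follows from the lower correlation and SD of the array, so it is no separate evidence. An exchanged label with a population that carried RFP was argued against by en, which lay 2.52 log2 units below the lowest array with RFP. RNA of another cell type could not be told apart, since the highest median among the marker lists was 0.63, for 3 fat body markers, between the bounds set for the test. A biological difference between larvae was not tested.

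Hemocyte markers were highest in delaminating replicate 2, with a median over 12 markers of 2.43 log2 units above the mean of the other delaminating arrays and 12 of 12 higher. Hemocyte RNA in that array is a candidate explanation, with the abundant transcripts PPO2 at 11.8, Pxn at 11.5, NimB4 at 10.8, He at 10.6 and Hml at 10.4, although the sort required RFP and GFP in each cell. Of the 12 markers, 2 lay above the median gene in posterior cells, and 1 stood in another list. A lower share of epithelial cells, which would raise all other types alike, was not seen in the other 5 marker lists, of which the highest median was 0.22 for muscle precursors. These lists could not exclude it. Above the median gene in posterior cells lay 6 of 6 trachea, 3 of 5 neuron, 3 of 8 muscle precursor, 2 of 4 glia and 0 of 3 fat body markers. Genes already bright in the sorted cells could stay level. Whether hemocytes adhere to delaminating cells in the disc was not tested.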

How the results depend on the processing

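Leaving out anterior 3 and delaminating 2 together was chosen only after the data had been seen, and the other alternatives were planned. Over all alternatives, 5889 values per gene, list, arm and count were labelled the same, 546 weaker, 161 stronger, 116 moved and 3 reversed. For genes, lists and arms, the same means that direction and side of the threshold were kept, weaker a lost call and stronger a gained one. Moved values changed sign without a call. Counts were labelled by their size relative to the main count. Values without a call had none to lose, so the total does not measure how stable the calls were. With a replicate block the counts were 66 genes in delaminating against posterior, 59 in posterior against anterior and 377 in delaminating against anterior cells, and 47, 54 and 351 of the genes called without it remained called. Of the named genes called, 13 of 25, 5 of 25 and 5 of 55 lost their call, and of the lists called the DNA replication list in posterior against anterior cells did. The numbers were not taken as pairs, since the labels name no shared source. The deviations of arrays with the same number had correlations from -0.12 to 0.181, not all above 0.1. A shared source per number was not excluded, though. Of 18 best matches between arrays 10 fell on the same number, against 6 by chance. Replicate 2 was also highest for most of the hemocyte markers in each group. The p values given elsewhere are unpaired and take no account of such a source. With one array left out, the counts ranged from 17 to 281, 35 to 88 and 212 to 567 in that order, lists called from 11 to 14, 6 to 13 and 13 to 22, arms from 0 to 1, and shared genes from 32 to 78. Array weights gave 749, 427 and 1974 genes, 6 lists in posterior against anterior cells and 336 shared genes, and weighted anterior 3 at 0.11 and delaminating 2 at 0.34. All probe sets gave 129 in posterior against anterior and 709 in delaminating against anterior cells. Only the groups compared gave 185 in delaminating against posterior and 180 in delaminating against anterior cells. Without anterior 3 and delaminating 2 there were 270 genes in delaminating against posterior cells, of which 95 were among the 96, and 6 lists in posterior against anterior cells and 2 arms. With an estimated correlation 0, 1 and 1 lists and 0 arms passed, without the dimmest 25% of genes 7 lists in posterior against anterior cells, and with quantile normalization 0 arms. The hemocyte list in delaminating against anterior cells turned downward with array weights (0.861), without both arrays (0.613) and without delaminating 2 (0.988, with 0.00147 as the lowest with one array left out). In delaminating against posterior cells an anterior array enters only through the shared spread. The rise to 281 genes came without anterior 3, whose values deviated most from their group mean, and fewer samples do not account for it. The cause of the other changes was not tested, except that all probe sets count more tests and a left-out array leaves fewer samples. Signal over background limits the dimmest genes, for which no detection calls were analysed here.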

Other observations

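The gene families, the single genes outside them and the tests of neighbouring genes were chosen after their results had been seen. Of 79 families of genes that share a name stem, 4 passed by camera in delaminating against posterior, 7 in posterior against anterior and 8 in delaminating against anterior cells, and with an estimated correlation the lowest adjusted p over all families was 0.233, 0.879 and 0.305 in that order. In delaminating against anterior cells, 4 of 27 measured Vps genes, which act in vacuolar protein sorting, were called higher, and the median log2 difference was 0.41 (camera adjusted p = 0.000608 over 79 families, adjusted p = 0.831 with an estimated correlation). Among called genes picked after their values were seen, with no list tested, log2 differences were 1.38 for Vps60 (adjusted p = 0.0115), 1.34 for Ist1 (0.0154), 1.20 for shrb (0.0277), 0.98 for TSG101 (0.0234) and 0.86 for Vps4 (0.0154). The 13 GstE genes, of glutathione transferases, had a median of 1.01 with 5 called higher (camera adjusted p = 0.000461, adjusted p = 0.762 with an estimated correlation). The 8 Mal-A genes, of maltases, had a median of -0.57 with 1 called lower (camera adjusted p = 0.000461, adjusted p = 0.305 with an estimated correlation). The other 5 were GstD (median 0.50, camera adjusted p = 0.000735), Cht (0.49, 0.00331), Polr (0.29, 0.0164), Rpn (0.40, 0.0428) and Sec (0.31, 0.0428), each with an adjusted p of 0.762 or 0.831 with an estimated correlation. In delaminating against posterior cells they were Mal-A (-0.63, 0.000258; adjusted p = 0.233 with an estimated correlation), GstD (0.41, 0.000294), Alp (-0.35, 0.00383) and GstE (0.24, 0.0367), the last 3 with an adjusted p = 0.968 with an estimated correlation. In posterior against anterior cells they were Nup (0.31, 0.0282), GstE (0.45, 0.0282), Eig (-0.47, 0.0282), dpr (-0.24, 0.0363), Gr (-0.07, 0.0363), Mst (-0.23, 0.0366) and Tsp (0.27, 0.0385), each with an adjusted p = 0.879 with an estimated correlation.

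Of further genes picked after their values were seen, with no list tested, Ddc, the dopa decarboxylase that makes dopamine, had in delaminating against anterior cells a log2 difference of 2.61 (adjusted p = 0.00365), yellow-b 2.60 (0.00756) and yellow-e 2.49 (0.000302). amd, a paralog of Ddc, had 0.93 (0.0459), and ple, the tyrosine hydroxylase of the same pathway, had signals of 3.44 and 3.42, below the arrays' lower quartiles.

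Among the 53 genes lower in both populations with RFP, neighbours on the chromosome recurred, with a run of 6 on 2L made of CG34169, Gr36a, Gr36b, Gr36c, Grl36a and beat-IIIc, and a run of 3 on X made of Hesr, Him and CG33639. On 2L, all but beat-IIIc lay between 4.01 and 5.59 in the arrays with RFP, below the lower quartiles. Grl36a lay at 5.81 to 6.44 even in anterior cells. Chance placement was argued against by 11 adjacent pairs, against a mean of 0.235 and a highest value of 3 in 10000 permutations that placed each gene on its own (permutation p = 1e-04, the smallest they can give). Whether the signal of the 2L genes follows muscle precursor cells stayed open. The correlation within groups over 9 arrays with the mean of htl, twi and Him was -0.20 (two-sided exact permutation p = 0.569, Spearman's rho -0.22 with exact permutation p = 0.63, and -0.27 without the 2 farthest arrays). It could not decide this, because in arrays with RFP the 2L genes other than beat-IIIc lay below the lower quartiles, as did htl at 3.78 to 4.85. A shared regulatory region that differs between anterior and posterior cells may also be a source, and no value here tests it. The log2 differences of beat-IIIc were -2.97 in posterior and -3.85 in delaminating against anterior cells.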
